A study of Mus musculus with 2 samples.

How the data were processed

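The deposited counts were UMI counts per gene and barcode, written by Cell Ranger 5.0.0 per the file headers. The submitters' processing notes name Seurat 3.2.3 and the mouse genome mm10, and the protocols name version 3.1 of the library kit. The annotation version was not given in the sources used here. Gene locations were taken from GENCODE vM21, in which 314 of 314 gene identifiers looked up carried the same symbol. Every deposited barcode had at least 500 UMIs. Cells with at least 200 genes and at most 10% mitochondrial UMIs were kept, which removed 1505 mock and 1439 PTIR1 cells. Doublets were scored with Scrublet through scanpy in each library. The automatic threshold called 0 of 9328 mock cells, and where it called under 0.5% the highest scores were removed instead, at 0.8% per 1000 cells, which removed 790 mock cells (8.47%). In the PTIR1 library the threshold called and removed 87 of 7567 cells (1.15%). The different rules are 1 of the settings varied below.

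Counts were scaled to 10000 per cell and logged, and 2000 variable genes were chosen within libraries, without mitochondrial, ribosomal, receptor segment, haemoglobin, Xist and cell cycle genes. Both libraries were clustered together without integration, with 30 components, 15 neighbours and Leiden clustering at resolution 1.0, and T and NK clusters were clustered again at resolution 1.0, which gave 34 clusters in all. A cluster was named when at least 3 markers of a class were present, each in at least 10% of its cells, above 2-fold over the rest and at no less than 20% of the highest cluster. A cluster was called mixed when another lineage had at least 50% of the leading share of markers, or when a lymphoid cluster had at least 25% of the macrophage marker level, a limit set after the data were seen. Clusters with a median depth under 1/3 of their library's median and no marker of the class among the 10 top genes (detected in at least 25% of cells) were left unnamed, as were those with more markers of another lineage among these genes. The 20 gene lists and 22 cell type lists were fixed before the data were examined. Mx1 and Ero1a had no row, 40 symbols were duplicated, and Aldoa was not used because more than 1 gene identifier carried it.

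Within a class, UMIs were summed over cells and divided by the class total to give CPM. List members with at least 50 UMIs over both libraries were measured, and for the ranking of single genes detection in at least 5% of cells of a library was required as well. A gene was called possible free RNA where its level was under 5% of that in the highest other class with at least 100 cells. RNA from other cells above that limit was not flagged. Ratios of CPM have exact conditional binomial intervals, levels exact Poisson intervals, and shares exact binomial intervals. Ratios of shares have approximate normal intervals on the log scale. List medians have intervals from 1000 Poisson draws and percentiles among 10000 random lists matched in 20 bins of expression. Medians with macrophage-like clusters, or groups of like immediate early RNA, weighing the same have intervals from 100 draws. The genes ranked first were the 12 in each direction in the CT26 tumour cell-like, macrophage-like, NK cell-like and CD4 T cell-like classes, and the 5 in each direction in the others, by the end of the interval nearest to 1. Regulatory T cells were joined with conventional CD4 T cells because their clusters did not part. List members given as examples were ranked in the same way. Cxcl10 in tumour cell-like cells, Arg1 and Cd40 in macrophage-like cells, Gzma, Gzmb, Gzmd, Gzme, Prf1 and Cxcl10 in NK cell-like cells, and Pdcd1, Gzmb, Gzme, Gzmf and Prf1 in CD8 T cell-like cells fell outside that order and were chosen as examples after their values were seen. Some genes that these rules select are not reported here. The median log2 ratio of all genes, from -0.10 in B cell-like to 0.01 in neutrophil-like cells, was left in the ratios.

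The code was tested on simulated data with 200 changed genes. Counts were independent Poisson draws for each gene, the spread that the intervals assume, so coverage near 95% checks the code only. Variation between cells, animals or libraries was not simulated, nor were genes of a list that change together. Intervals covered the true ratio for 95.5% of unchanged and 95.3% of changed genes at macrophage-like depth (11582 genes), 95.6% and 92.9% at tumour cell-like depth (10445 genes), and 95.7% and 96.2% at NK cell-like depth (9398 genes). A list with a true log2 ratio of -1 had medians of -0.95, -1.07 and -1.05, and 6.5%, 2.0% and 4.0% of 200 unchanged lists fell beyond the outer 2.5% on either side. In total 21 other settings were chosen in advance and 9 were added after the data were seen. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9 were used.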

Results

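The series compared cells taken from CT26 tumours grown in BALB/c mice, a common inbred laboratory strain. CT26 is a mouse colon carcinoma cell line that grows as a transplanted tumour in that strain. The tumours carried either a mock construct or PTIR1, a factor that the series title describes as a suppressor of the immunoproteasome. Droplet-based 3' single-cell RNA sequencing was used, in which each captured transcript carries a unique molecular identifier (UMI). There were 2 libraries, 1 mock and 1 PTIR1, so there was no replicate, no significance test of a difference between the groups was made, and every interval below is a 95% interval that covers counting error only. The mock library held 10833 cells and 95166611 UMIs, with a median of 2357 UMIs and 1021 genes per cell. The PTIR1 library held 9006 cells and 98540561 UMIs, with a median of 4933 UMIs and 1710 genes per cell. After filtering, 8538 mock cells (median 3231 UMIs) and 7480 PTIR1 cells (median 6924.5 UMIs) were kept. PTIR1 itself could not be used to check the labels, because 0 of the 32285 gene rows carried that name, and its level was not analysed here. The labels describe the source as tumour-infiltrating lymphocytes, and the libraries also held macrophage-like, neutrophil-like, fibroblast-like and tumour cell-like cells.

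The first comparison asked which cell classes made up each library. Whether cells were sorted or enriched before capture, and alike for both libraries, was not given in the sources used here, so a share describes the cells captured and not the tumour. CD8 T cell-like cells, the class that holds cytotoxic T cells, formed a smaller share of the PTIR1 library, and fibroblast-like cells a much larger one. B cell-like, NK cell-like and neutrophil-like shares were larger in the PTIR1 library. Mast cell or basophil-like and macrophage-like shares were smaller. There were 117 CD8 T cell-like cells in the mock library (1.37% of kept cells, exact binomial interval 1.13 to 1.64%) and 24 in the PTIR1 library (0.321%, 0.206 to 0.477%). The share was 4.27-fold lower in the PTIR1 library (interval 2.76 to 6.62). Among all T cell-like cells, CD8 T cell-like cells made up 43.5% (37.5 to 49.7%) of 269 in the mock library and 16.3% (10.8 to 23.3%) of 147 in the PTIR1 library. With a mixed cluster of T cell-like cells with macrophage markers counted as CD8 T cell-like, these shares were 55.0% of 338 and 33.5% of 185. CD4 T cell-like cells, in which regulatory and conventional cells did not part into separate clusters, made up 1.60% and 1.34%, and the interval of their log2 ratio ran from -0.63 to 0.11. Over all kept cells, Cd8a, which encodes a chain of the CD8 co-receptor, was 3.78-fold lower in the PTIR1 library in counts scaled to a common total (CPM) (3.46 to 4.13). Cd8b1, which encodes the partner chain, was 2.15-fold lower (1.995 to 2.308), and Foxp3, the regulatory T cell transcription factor, was 1.16-fold lower (0.969 to 1.39).

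NK cell-like cells made up 6.32% of the mock and 9.06% of the PTIR1 library, a ratio of 1.43 (1.29 to 1.60). The difference was smaller as a share of named cells, since more mock cells had no class. A cluster split from the T and NK cells, with Trdc, Ncr1 and Klrd1 among its top genes, was left without a class. It held 115 mock and 11 PTIR1 cells. B cell-like cells made up 4.66% and 9.26%, a ratio of 1.99 (1.76 to 2.24). Neutrophil-like cells made up 2.25% and 4.09%, a ratio of 1.82 (1.52 to 2.17). Macrophage-like cells, from which monocyte-like cells did not part, were the largest named class, with 31.2% of the mock and 25.4% of the PTIR1 library. Mast cell or basophil-like cells were 3.21-fold lower in the PTIR1 library (2.45 to 4.21), at 2.83% against 0.882%. Fibroblast-like cells numbered 46 in the mock and 853 in the PTIR1 library (0.539% against 11.4%), a ratio of 21.2 (15.8 to 28.4). Conventional dendritic cell-like cells made up 1.46% and 1.51%. CT26 tumour cell-like cells made up 2.35% and 1.94%, with an interval of their log2 ratio from -0.59 to 0.02. Plasmacytoid dendritic cell-like cells made up 1.12% and 1.75%. Clusters without a class held 41.7% of the mock and 25.5% of the PTIR1 cells, most of them at low depth, and 1.84% and 5.87% of cells lay in clusters with markers of more than 1 lineage.

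Several shares moved with the processing. Counting the same mixed cluster (0.81% of mock and 0.51% of PTIR1 cells) as CD8 T cell-like brought the log2 ratio of that class from -2.09 to -1.39, and clustering each library on its own brought the fibroblast-like log2 ratio from 4.40 to 1.83. The log2 ratio was -0.04 for NK cell-like cells as a share of lymphoid cells, 0.04 for macrophage-like cells with a mitochondrial share of up to 20%, and between -0.38 and -0.03 for plasmacytoid dendritic cell-like cells under 4 alternatives, each of the opposite sign to the value given above.

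**Figure D1:**
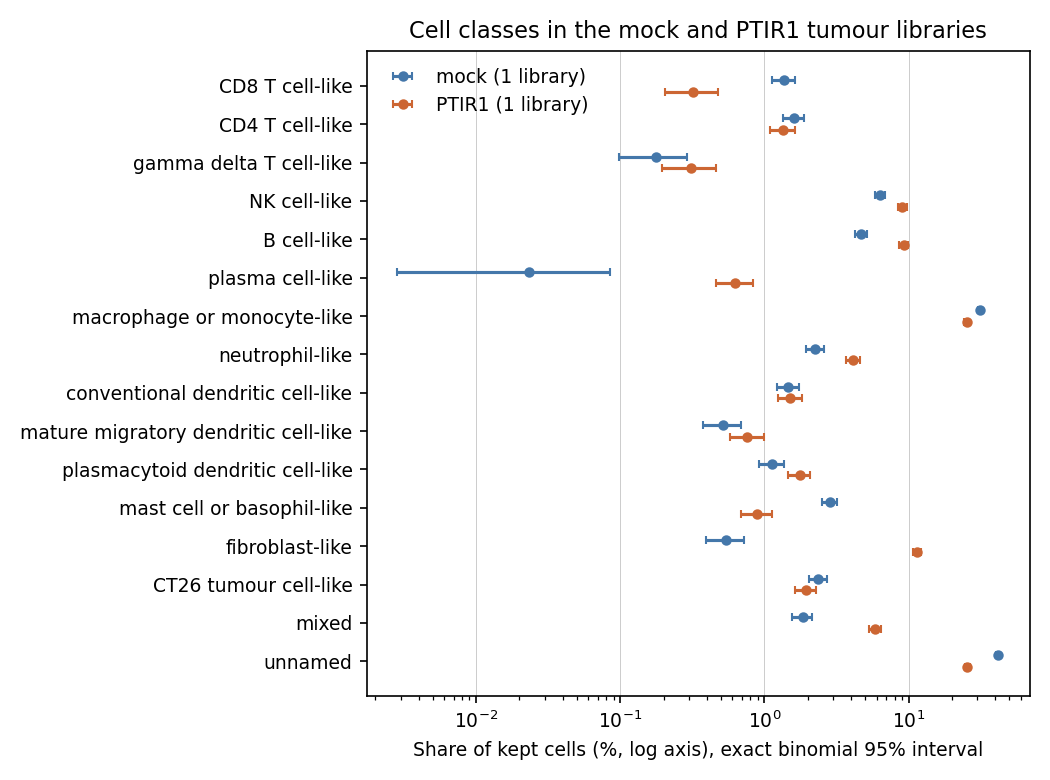
Share of kept cells in each cell class (percent, log axis) for the mock and the PTIR1 library, 1 library each, with exact binomial 95% intervals as bars. CD8 T cell-like cells lie at 1.37% and 0.321%, and fibroblast-like cells at 0.539% and 11.4%.

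The second comparison concerned the tumour cells themselves, labelled as expressing PTIR1 in that library, and the immunoproteasome named in the series title. The immunoproteasome is the form of the proteasome whose catalytic subunits are induced by interferon and which generates many peptides for MHC class I. All 5 measured immunoproteasome genes were lower in the CT26 tumour cell-like cells of the PTIR1 library, whereas 4 of 7 genes of the constitutive proteasome were higher and 3 lower. Interferon gamma response, MHC class I, hypoxia, glycolysis and cell cycle genes were lower as well, and immediate early genes were higher. The class rested on 201 mock and 145 PTIR1 cells, with median depths of 72057 and 55453 UMIs, and was named from Krt18, Tm4sf1 and Areg. Psmb9 (ENSMUSG00000096727, minus strand of chromosome 17, 34181987 to 34187764 in mm10) encodes a catalytic subunit and stood at 180.5 CPM in the mock and 71.3 CPM in the PTIR1 cells, 2.53-fold lower (2.34 to 2.74). Psmb8 (ENSMUSG00000024338, plus strand of chromosome 17, 34197721 to 34201454), another catalytic subunit, was 1.98-fold lower (1.85 to 2.12). The median log2 ratio of the 5 genes was -0.38 (-0.50 to -0.28), at percentile 0.28 of 10000 random lists matched on expression. These percentiles, here and below, describe these libraries only. The constitutive proteasome had a median of 0.00 (-0.05 to 0.04). The immunoproteasome median came to -0.15 when each cell weighed the same. It came to -0.11 over the 3 of 5 genes still measured with each cell thinned to 1000 UMIs, which also weighs each cell the same. At that depth a Psmb9 UMI was seen in 11.4% of mock and 4.14% of PTIR1 cells, and a Psmb8 UMI in 16.4% and 11.7%. For Psmb10 the shares were 9.45% and 8.97%. The exact binomial intervals of the mock and PTIR1 shares overlap for each of these genes.

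In the same cells, 11 of 12 MHC class I presentation genes were lower, with a median log2 ratio of -0.44 (-0.49 to -0.36), and -0.24 when each cell weighed the same. Tap1 and Tap2, which encode the peptide transporter, had ratios of PTIR1 over mock of 0.579 and 0.644, and H2-T23 had 0.654. The member that was higher, H2-Q7, stood at a level that RNA from other cells alone can reach. At an equal depth of 1000 UMIs a Tap1 UMI was seen in 3.98% of mock and 4.83% of PTIR1 cells, and an H2-K1 UMI in 56.2% and 50.3%. Of 16 interferon gamma response genes 15 were lower, with a median of -1.15 (-1.29 to -0.97), below all random lists, and with a median of -0.75 when each cell weighed the same. The guanylate-binding protein genes Gbp4, Gbp2 and Gbp3 were 5.19-fold, 3.21-fold and 2.998-fold lower. Cxcl10, a chemokine gene, had a ratio of 0.396. Type I interferon response genes were lower in 14 of 16, with a median of -0.58, and -0.28 when each cell weighed the same, led by Ifi44 and Ifit3. Hypoxia and angiogenesis genes were lower in 10 of 11, with a median of -0.64 (-0.81 to -0.57), and -0.99 when each cell weighed the same, among them Bnip3 (ratio 0.375), Pgk1 (0.432) and Ndrg1 (0.502). All 10 glycolysis genes were lower (median -0.41), with ratios of 0.700 for Tpi1 and 0.715 for Pkm. Cell cycle genes were lower in 17 of 18 (median -0.53, and -0.24 over the 4 genes measured at 1000 UMIs per cell), with ratios of 0.481 for Mki67 and 0.567 for Top2a. Immediate early and stress genes, which can also respond to tissue dissociation, were higher in 11 of 14 (median 0.69), with Zfp36 2.48-fold and Fos 2.31-fold higher.

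Among the genes ranked first in the tumour cell-like class, Car9, the hypoxia-induced carbonic anhydrase, was 23.8-fold lower (11.9 to 55.6), with 334 UMIs in the mock and 8 in the PTIR1 cells. Cnfn was 17.4-fold lower (10.3 to 32.1) and Slurp1 6.20-fold lower (5.50 to 7.02). Ubd, a ubiquitin-like gene induced by interferon, had 71 UMIs against 1. Ankrd37, Gbp2b, Ly6a and Apol9b were 4.15-fold, 3.52-fold, 2.85-fold and 2.89-fold lower. Krt8, a keratin gene of simple epithelia and itself a tumour marker in the fixed lists, was 18.1-fold higher (10.0 to 36.0), from 0.659 to 11.95 CPM. Crip1 was 5.70-fold higher (5.26 to 6.18). The extracellular matrix genes Col6a2, Dpt and Col3a1 were 29.8-fold (9.65 to 149), 10.5-fold and 3.66-fold higher, and Fabp4, Tppp3, Ptgis, Dqx1, Plat, Platr3 and Fgf21 were between 4.584-fold and 7.496-fold higher. Fibroblast marker CPM in this class, Col3a1 included, were 1.22 times as high in the PTIR1 library (1.18 to 1.25) and macrophage marker UMIs 1.22 times as high (1.19 to 1.26). The fibroblast markers already stood at 620.4 CPM in the mock cells of this class. This ratio therefore cannot show how much fibroblast RNA was added in the PTIR1 library.

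The third comparison asked how macrophage-like cells differed, the class with the most cells (2663 mock, 1899 PTIR1, median depths of 13027 and 12503 UMIs). Interferon gamma response, MHC class II, MHC class I and immunoproteasome genes were lower in the PTIR1 library. Chemokine genes for neutrophils and monocytes, and several genes of alternatively activated macrophages, were higher. The largest cluster of the mock class (1167 mock and 515 PTIR1 cells) was led by Lyz2, Msr1 and Csf1r, and that of the PTIR1 class (673 and 835) by Cxcl3, Thbs1 and Arg1. A cluster led by interferon-induced genes such as Rsad2 and Cxcl10 held 380 mock and 194 PTIR1 cells. Neutrophil marker UMIs in this class were 2.57 times as high, in CPM, in the PTIR1 library, CT26 tumour marker UMIs 3.19 times and fibroblast marker UMIs 4.63 times, whereas mast cell marker UMIs were 0.316 times as high.

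All 15 measured interferon gamma response genes were lower in macrophage-like cells, with a median log2 ratio of -1.02 (-1.08 to -0.98), below all random lists. Cxcl9 (ENSMUSG00000029417, minus strand of chromosome 5, 92321347 to 92328079), which encodes a chemokine that attracts T cells, stood at 493 CPM in the mock and 115.2 CPM in the PTIR1 cells, 4.28-fold lower (4.12 to 4.45). Iigp1, an interferon-inducible GTPase gene, was 3.31-fold lower (3.08 to 3.57), and Gbp2 and Gbp4 had ratios of 0.397 and 0.398. At an equal depth of 1000 UMIs, 14.0% of mock (12.7 to 15.4%) and 4.63% of PTIR1 macrophage-like cells (3.72 to 5.68%) had a Cxcl9 UMI. In B cell-like cells at the same depth the shares were 4.08% and 1.01%. MHC class II genes were lower in 8 of 9 (median -1.09, -1.11 to -1.06), and within the largest clusters of the mock and of the PTIR1 class, which hold most of the cells, their medians were -0.42 and -0.51. Ciita, the master regulator of class II expression, was 2.83-fold lower (2.47 to 3.26), H2-Eb1 had a ratio of 0.436 and H2-Ab1 one of 0.450. At equal depth, 35.7% of mock and 19.6% of PTIR1 cells had an H2-Ab1 UMI. All 5 immunoproteasome genes were lower (median -0.66, -0.68 to -0.61), with ratios of 0.560 for Psmb9 and 0.633 for Psmb8. Their median was -0.51 and -0.31 within the same pair of largest clusters, and -0.26 in the group of cells with the most immediate early RNA. All 12 MHC class I genes were lower (median -0.45, and -0.25 and -0.31 within those clusters), led by Nlrc5 (ratio 0.495), the class I transactivator, and H2-Q7 (0.576). The 7 constitutive proteasome genes were lower by less (median -0.09, percentile 19.1), and 15 of 16 type I interferon response genes were lower (median -0.39, and -0.09 with each cluster weighing the same).

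Chemokine genes that recruit neutrophils and monocytes were higher in 7 of 8 in macrophage-like cells (median 0.80, 0.79 to 0.81). Their median was 0.29 and 0.24 within the same pair of largest clusters, 0.52 with each cluster weighing the same, and -0.04 in the group of cells with the least immediate early RNA. Cxcl5 was 4.71-fold higher (4.19 to 5.30), Cxcl1 2.80-fold, Cxcl3 2.56-fold and Cxcl2 2.32-fold, whereas Ccl8 was lower, at 246.7 CPM in the mock and 123.3 CPM in the PTIR1 cells. Among 13 genes of alternatively activated macrophages 11 were higher (median 0.43, and 0.17 with each cluster weighing the same). Retnla had 0 UMIs in the mock and 1025 UMIs (39.4 CPM) in the PTIR1 cells, Cd163 was 6.76-fold higher (4.86 to 9.59), and Chil3 4.15-fold higher (3.90 to 4.41). Chil3 is also a monocyte marker in the fixed lists and a top gene of a mixed cluster with immature neutrophil genes, held almost only by the PTIR1 library. Arg1, which encodes arginase, was 1.37-fold higher, and 38.8% of mock and 50.2% of PTIR1 cells had an Arg1 UMI at equal depth, against 4.59% and 9.84% of B cell-like cells. Genes of inflammatory macrophages went both ways: 7 of 13 were higher, among them Il1a (3.42-fold), Il6 (3.27-fold) and Ccl3 (2.20-fold), and 6 lower, among them Cxcl9 and Cd40 (ratio 0.474). Their median of 0.22 became -0.08 with each cluster weighing the same and -0.14 within cells of like immediate early RNA. Immediate early genes were higher in 14 of 15 (median 0.55), led by Egr1 (3.096-fold) and Nr4a1 (2.46-fold). Cell cycle genes were lower in 16 of 18 (median -0.52), and their median became -0.07 with at least 500 genes per cell and 0.05 within cells of like immediate early RNA.

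Further genes ranked first in the macrophage-like class included Ctsk, the cathepsin of bone-resorbing cells, which was 10.2-fold higher (9.30 to 11.3), and Acp5, a phosphatase of the same cells, which was 6.79-fold higher (6.18 to 7.48). Wfdc21, also a top gene of the mixed cluster with immature neutrophil genes, was 11.2-fold higher. Areg, which encodes the growth factor amphiregulin and is also a tumour cell marker here, was 7.85-fold higher. Ednrb, Mmp9, Klk8 and Lsmem1 were between 3.33-fold and 5.90-fold higher. Ly6a, Serpina3g, Calhm6 and Selenom were 3.69-fold, 3.64-fold, 3.51-fold and 3.29-fold lower. Slamf7 and Slamf8, receptors of one family, were 3.51-fold and 3.15-fold lower, and Gbp2b, Gbp6 and Tgtp2, GTPase genes induced by interferon, were between 2.79-fold and 2.92-fold lower.

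**Figure D2:**
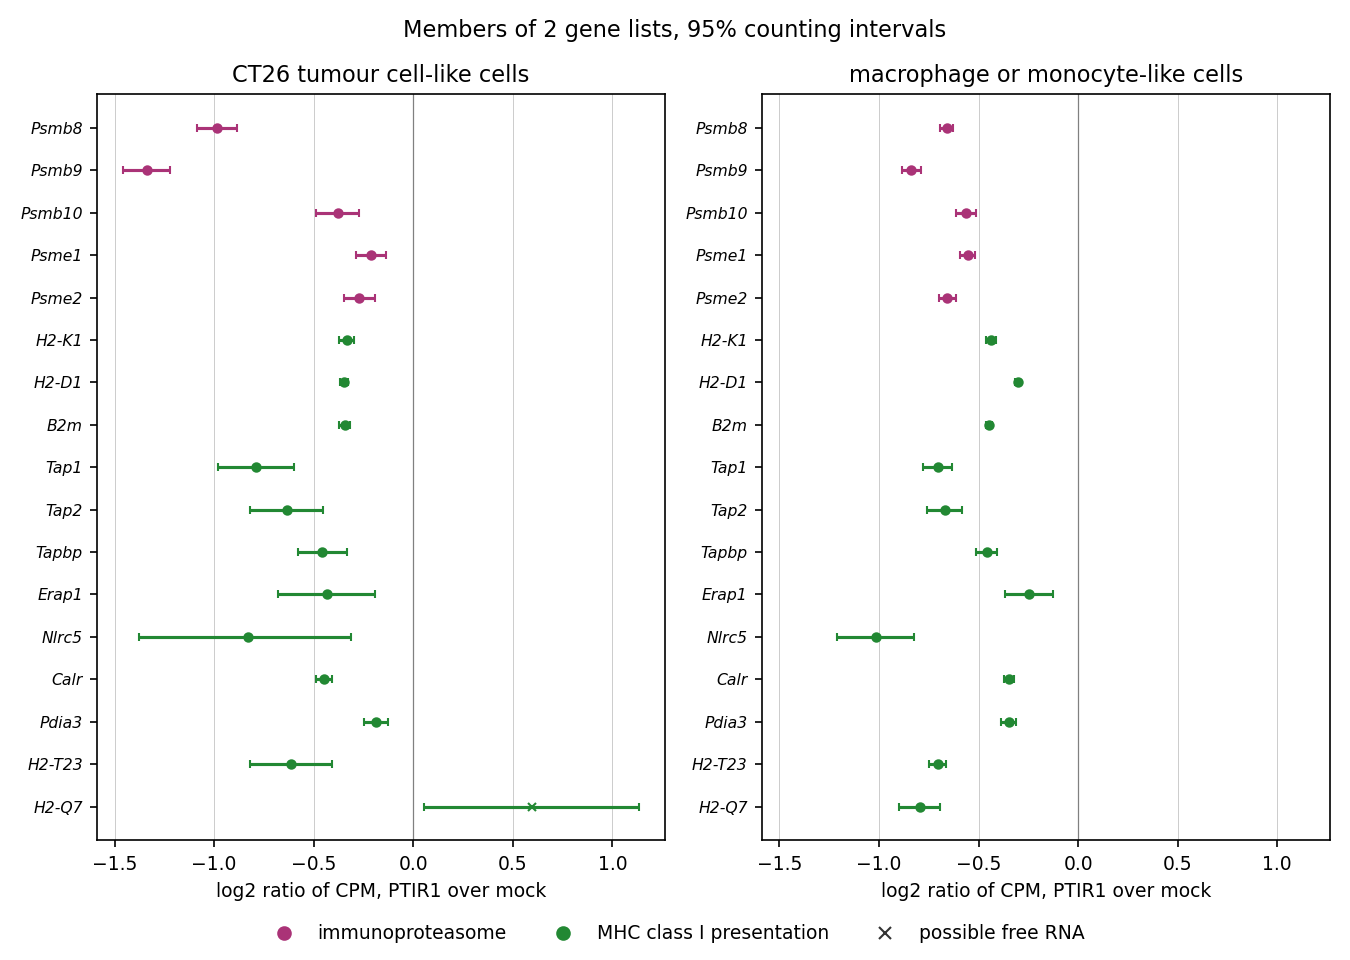
Log2 ratio of CPM, PTIR1 over mock, for each measured member of the immunoproteasome and MHC class I lists in CT26 tumour cell-like and macrophage-like cells, 1 library per group, with 95% counting intervals as bars. Crosses mark genes at a level that RNA from other cells alone can reach, and every member lies below 0 in macrophage-like cells.

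The same question was put to the other myeloid classes. In neutrophil-like cells (192 mock, 306 PTIR1) all 14 interferon gamma response genes were lower, with a median log2 ratio of -1.50 (-1.63 to -1.34), and all 16 type I interferon response genes were lower (median -1.05, -1.21 to -0.91). Cxcl9 was 10.4-fold lower (8.01 to 13.6), Gbp3 5.11-fold lower and Ly6a 7.16-fold lower. The antiviral genes Ifit1 and Rsad2 had ratios of 0.294 and 0.358. All 5 immunoproteasome genes were lower (median -0.69, and -0.41 with at least 500 genes per cell), with a ratio of 0.507 for Psmb9, and MHC class I genes were lower in 11 of 12 (median -0.59). MHC class II genes were lower in 6 of 7 (median -1.14), and came to -0.66 when each cell weighed the same. Chemokine genes were higher in 7 of 8 (median 1.19): Ccl2, Cxcl1 and Ccl7, attractants of monocytes and neutrophils, were 3.02-fold, 3.16-fold and 2.54-fold higher, and their list came to 0.67 when each cell weighed the same. All 6 genes of the alternatively activated macrophage list were higher (median 1.06), with Chil3 11.5-fold higher (4.76 to 36.0) on 5 and 109 UMIs. Chil3 is also a monocyte marker in the fixed lists and a top gene of a mixed cluster with immature neutrophil genes. That cluster was held almost only by the PTIR1 library, so Chil3 does not set alternative activation apart here. C1qa, a complement gene of macrophages, was 3.18-fold higher, with a log2 ratio of -0.29 when each cell weighed the same, and Mmp12 and Fabp5 were 7.19-fold and 3.82-fold lower. Macrophage marker UMIs in this class were 1.45 times as high, in CPM, in the PTIR1 library, and neutrophil marker UMIs 0.722 times. The macrophage markers stood at 3325 CPM in the mock and 4809 CPM in the PTIR1 cells, against 6813 and 7196 CPM in macrophage-like cells. In the median cell of the neutrophil-like cluster they made up 0.0847% of UMIs. Macrophage RNA in some of these cells can therefore weigh on the sums, and how much of the list values it carries was not tested.

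In conventional dendritic cell-like cells (125 mock, 113 PTIR1) 13 of 15 interferon gamma response genes were lower (median -0.79, -0.90 to -0.67), with ratios of 0.332 for Gbp4 and 0.357 for Iigp1. All 12 MHC class I genes (median -0.28) and all 5 immunoproteasome genes (median -0.20) were lower, Psmb10 with a ratio of 0.638. MHC class II genes, which mark the antigen-presenting function of these cells, were close to even (7 of 9 lower, median -0.08), and their median became 0.37 with doublets kept and 0.48 with a mitochondrial share of up to 20%. Chemokine genes were higher in 5 of 7 (median 1.14), with Cxcl1 8.86-fold higher (6.56 to 12.2), and their median came to 0.01 with a mitochondrial share of up to 20%. All 15 immediate early genes were higher (median 0.61). Areg, Ear2, Ccr7 and Pf4 were 32.5-fold (8.59 to 275), 5.46-fold, 4.45-fold and 3.76-fold higher, and Ccl5, Ly6a, Fpr2 and Ly6c2 were 4.57-fold, 2.80-fold, 3.96-fold and 2.82-fold lower. Fibroblast marker UMIs in this class were 9.76 times as high, in CPM, in the PTIR1 library, and CT26 tumour markers, which include Areg, 4.11 times.

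**Figure D3:**
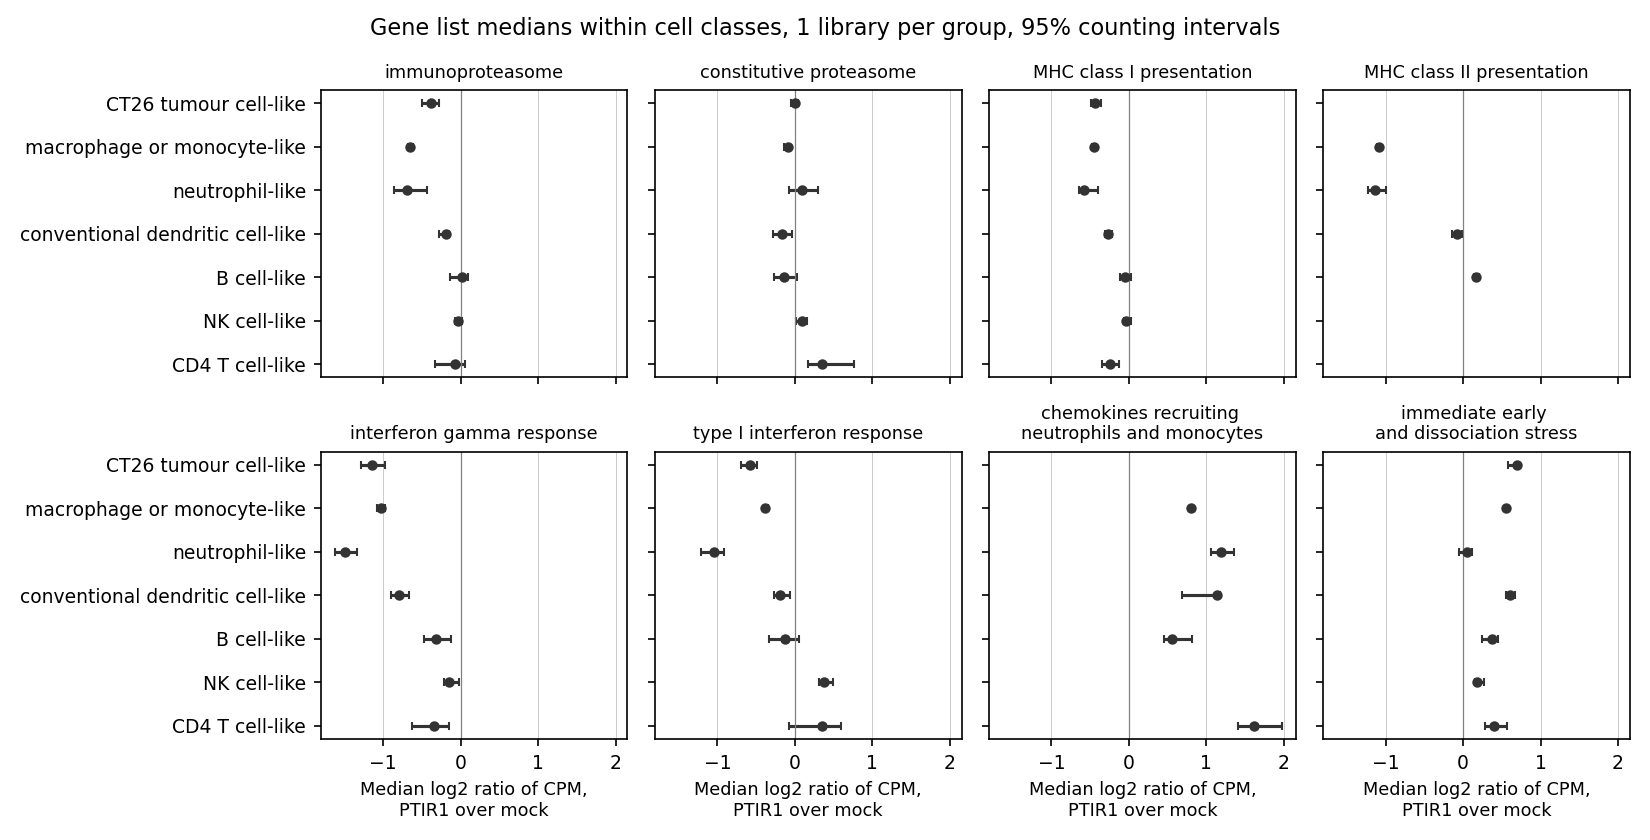
Median log2 ratio of CPM, PTIR1 over mock, of 8 gene lists (panels) within 7 cell classes (rows), 1 library per group, with 95% counting intervals as bars. Lists are left out where most members stand at a level that RNA from other cells alone can reach, and the interferon gamma response median is below 0 in each class, from -1.50 in neutrophil-like to -0.15 in NK cell-like cells. Lists that stay in can still hold such RNA. Macrophage marker CPM were 6813 in mock and 7196 in PTIR1 macrophage-like cells. In the same order they were 3325 and 4809 in neutrophil-like and 1327 and 1369 in conventional dendritic cell-like cells. B cell-like cells had 778.4 and 1148, and CD4 T cell-like cells 521 and 1195. Tumour cell-like cells had 584.8 and 714.2, and NK cell-like cells 162.6 and 299.5.

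The cytotoxic lymphocytes were compared next. NK cell-like cells (540 mock, 678 PTIR1, median depths of 8053 and 8739 UMIs) showed higher Gzmg and Gzmf, which encode granzymes, an even cytotoxic list as a whole, higher type I interferon response genes and little difference in the immunoproteasome. Gzmg (ENSMUSG00000040284, minus strand of chromosome 14, 56156582 to 56159579) was 26.0-fold higher (21.5 to 31.7), from 19.7 to 513 CPM. The other granzyme genes Gzmf, Gzmc, Gzmd, Gzme, Gzmb and Gzma had ratios of 4.39, 1.64, 1.59, 1.43, 1.08 and 0.915, and Prf1, which encodes perforin, one of 1.10. The whole cytotoxic list was close to even (11 of 18 higher, median 0.03), with a median of -0.05 when each cell weighed the same. At equal depth 71.3% of PTIR1 and 72.3% of mock NK cell-like cells had a Gzmb UMI, against 4.92% and 4.85% of B cell-like cells. Ifng, which encodes interferon gamma, was 1.23-fold higher in NK cell-like cells of the PTIR1 library (1.10 to 1.38). In the mixed clusters, which include NK cell-like cells with macrophage markers, its ratio was 0.767 (0.681 to 0.864). Type I interferon response genes were higher in 14 of 15 (median 0.38, 0.31 to 0.49), with Ifit3 2.13-fold and Isg15 1.64-fold higher. Interferon gamma response genes were lower in 10 of 15 (median -0.15), although Cxcl10 was 2.92-fold higher, and the 5 immunoproteasome genes had a median of -0.04 (-0.08 to 0.02). The interferon gamma response median was -0.08 centred on all genes and -0.21 when each cell weighed the same.

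Hilpda, a lipid droplet gene induced by hypoxia, was 2.24-fold higher in NK cell-like cells, and Pdgfa, Ly6c1, Nr4a1, Serpinb9b, Hist1h2bc, AA467197 and Apoe were between 1.82-fold and 2.64-fold higher. Itga1, an integrin gene of tissue-resident NK and innate lymphoid cells, was 1.90-fold lower (1.68 to 2.14), and Ifitm1 and Ifitm2, Hopx, Igflr1, Lpar6, Cdk14, Mcm10, Utp14b, Pls3 and Acp5 were between 1.74-fold and 3.77-fold lower. Ctsk was 3.16-fold lower, with a log2 ratio of 0.46 when each cell weighed the same. Macrophage marker UMIs in this class were 1.84 times as high, in CPM, in the PTIR1 library. A mixed cluster of NK cell-like cells with macrophage markers, kept out of the class, held 1.02% of mock and 4.57% of PTIR1 cells. Its median depth was 26695 UMIs, and doublet removal had taken 8.47% of mock but 1.15% of PTIR1 cells. Whether remaining doublets account for the difference was not tested.

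CD8 T cell-like cells numbered only 24 in the PTIR1 library, so their gene lists were computed after the data were seen and no single genes were ranked. Interferon gamma response genes were lower in 7 of 9 (median -0.87, -1.37 to -0.38), and came to -0.45 over the 4 genes with at least 200 UMIs. Genes of T cell exhaustion and checkpoints, which mark chronic stimulation, were higher in 8 of 12 (median 0.25, 0.07 to 0.54, and 0.47 when each cell weighed the same). Over the 3 genes measured at 1000 UMIs per cell their median was 0.81. Rgs16, Ctla4 and Nr4a2 were 2.44-fold, 2.01-fold and 1.63-fold higher, and Pdcd1, which encodes PD-1, had a ratio of 0.739 (0.549 to 0.980). At equal depth 22.2% of mock (15.1 to 30.8%) and 30.4% of PTIR1 cells (13.2 to 52.9%) had a Pdcd1 UMI (0% and 0.434% of B cell-like cells). These intervals overlap, so the Pdcd1 shares set no direction. The cytotoxic list had a median of 0.05 (-0.19 to 0.16) and went both ways, with a median of 0.30 when each cell weighed the same and 0.53 over the 8 genes measured at 1000 UMIs per cell. Ccl3, Ccl4, Prf1 and Gzmb had ratios of 4.83, 3.59, 1.64 and 1.47, and Gzme and Gzmf ratios of 0.265 and 0.362, the reverse of Gzmf in NK cell-like cells. Macrophage marker UMIs in this class were 3.35 times as high, in CPM, in the PTIR1 library, and neutrophil marker UMIs 0.203 times.

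CD4 T cell-like cells (137 mock, 100 PTIR1, median depths of 3986 and 3424 UMIs) had lower naive and memory genes, in 8 of 10 (median -0.49, -0.67 to -0.34), led by Tcf7, a transcription factor gene of naive and memory T cells (2.23-fold lower, 1.47 to 3.47), and Ltb (ratio 0.658). Genes of regulatory T cell activation were lower in 6 of 9 (median -0.29), with Il2ra, the interleukin 2 receptor alpha chain gene, 2.03-fold lower and Tnfrsf4 at a ratio of 0.623. With each cell thinned to 1000 UMIs these medians were 0.08 and 0.09, over the 4 and 5 genes still measured. Thinning also weighs each cell the same and leaves out cells under 1000 UMIs, so genes, cells and their weights differed at once. The naive and memory median was -0.005 with a mitochondrial share of up to 20%, and that of regulatory activation -0.03 when each cell weighed the same. The list medians thus depended on the measure. At equal depth an Il2ra UMI was seen in 13.6% of mock (7.95 to 21.1%) and 23.7% of PTIR1 cells (14.7 to 34.8%). In B cell-like cells the Il2ra shares were 0.510% and 0%. A Tnfrsf4 UMI was seen in 25.4% (17.9 to 34.3%) and 31.6% (21.4 to 43.25%), and a Ctla4 UMI in 16.9% (10.7 to 25.0%) and 30.3% (20.25 to 41.9%). The intervals of the mock and PTIR1 shares overlap for each gene, so these shares set no direction. Here and above, cells under 1000 UMIs were left out of shares at equal depth, 19 mock and 24 PTIR1 cells in this class. Interferon gamma response genes were lower in 11 of 13 (median -0.35, -0.63 to -0.15, and -0.10 with doublets kept), with Irf1 2.02-fold lower. Igfbp4, Ly6a, Dnah8, Ly6c1, Lrif1 and Gbp6 were between 2.54-fold and 4.53-fold lower, and Ccl5 and Gimap7 1.85-fold and 1.86-fold lower. The genes ranked highest were mostly genes of other cells: Cxcl2, Ccl9, Ccl7, Ccl6, Spp1, Lgmn and Thbs1, typical of macrophages, were between 2.87-fold and 6.29-fold higher, Cd79a and Cd74, genes of B cells, 4.57-fold and 2.89-fold, and Osm, Serpinb6b and Gzma 6.15-fold, 5.04-fold and 3.16-fold. In this class macrophage marker UMIs were 2.30 times and B cell marker UMIs 2.73 times as high, in CPM, in the PTIR1 library, and T cell marker UMIs 0.786 times.

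In B cell-like cells (398 mock, 693 PTIR1) interferon gamma response genes were lower in 12 of 14 (median -0.32, -0.47 to -0.12, -0.17 over the 4 with at least 200 UMIs and -0.55 with doublets kept), with a ratio of 0.722 for Irf1. MHC class II genes were higher in 7 of 9 (median 0.17, 0.14 to 0.21), with H2-Aa 1.19-fold higher. Under other settings their median ran from 0.06 with a mitochondrial share of up to 20% to 0.27 centred on all genes. Immediate early genes were higher in 11 of 15 (median 0.37, and between 0.15 and 0.20 under 4 other settings), among them Nr4a1 and Egr1, which antigen receptor signalling induces, at 2.87-fold (2.49 to 3.32) and 2.66-fold (2.43 to 2.90). B3gnt7, Hs3st1 and Cxcl1 were 5.69-fold, 3.16-fold and 4.07-fold higher. Igkc, the kappa light chain constant gene, was 1.94-fold lower (1.90 to 1.98), Ly6d 2.06-fold lower, and AI467606, Akap12 and Bcl7a between 2.45-fold and 3.69-fold lower. Fibroblast marker UMIs in this class were 4.91 times as high, in CPM, in the PTIR1 library, and B cell marker UMIs 0.833 times.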

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

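The tests of the CD8 share among T cell-like cells, with and without the mixed cluster, of Cd8a, and of Ifng outside mixed clusters were chosen after the result was seen, and the weightings by cluster and by immediate early RNA were added after the data were seen. Among the clusters outside every class, only those larger in the PTIR1 library were looked for here. Of these, 4 were held almost only by the PTIR1 library, so each can be a feature of that library alone. The largest held 10.05% of PTIR1 and 0.81% of mock cells (752 and 69), with a median of 1298 UMIs. Its top genes were S100a8, S100a9, Lars2, Gm42418, Mgp, AY036118, Cxcl3, Cxcl1, Ccl4 and Ccn1. Lars2, Gm42418 and AY036118 were also among the top genes of shallow clusters without a class, with medians of 760 and 1240 UMIs. Another held 1.79% and 0.15% (134 and 13 cells, median 861 UMIs), with the B cell genes Ebf1, Ralgps2 and Bank1. A cluster with Rsad2, Cxcl10, Mmp9 and Arg1 held 1.52% and 0.01% (114 cells and 1). The last held 0.79% and 0.01% (59 cells and 1), with the genes of immature neutrophils Camp, Ngp, Ltf and Lcn2. No explanation was tested for these clusters.

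The lower interferon gamma response of macrophage-like cells was set against 3 technical explanations and 1 biological one. A different mix of clusters is excluded as the whole cause, since the median log2 ratio was -0.767 (-0.879 to -0.719) with each cluster weighing the same, although it was smaller than over all cells. A difference in immediate early RNA is excluded in the same sense by -0.947 (-1.03 to -0.893) within cells of like immediate early RNA, although in the group of cells with the most of that RNA the median was -0.467 (-0.651 to -0.374). That RNA is only a stand-in for dissociation stress. Handling that differed between the libraries and left no trace in these genes stays open. In cells thinned to 1000 UMIs the median was -0.863 (-1.087 to -0.766). Random thinning keeps the expected proportions within each cell, so this value cannot decide on depth. The median depths of the class were 13027 UMIs in the mock and 12503 in the PTIR1 library. Less Ifng transcript in the PTIR1 tumour and an equal amount of it cannot be told apart: the ratio of Ifng CPM was 1.093 (1.023 to 1.168) over all kept cells, but 0.932 (0.859 to 1.011) outside the mixed clusters, which hold 827 of 1972 PTIR1 and 424 of 1626 mock Ifng UMIs. The bound of 1 set before was wrong for that reason, since the side of 1 rests on which captured cells are counted, and whether capture was alike is not known. Doublets were also removed by different rules in the mock and the PTIR1 library, which can bear on the mixed clusters.

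The smaller CD8 T cell-like share was set against CD8 T cells left outside the class and against dilution. Cells left outside the class are excluded as the whole cause by the log2 ratio of Cd8a over all kept cells, -1.917 (-2.044 to -1.791). How much of the difference they account for stays open: the interval of Cd8b1, -1.101 (-1.206 to -0.997), holds the bound of -1, so a smaller share and cells left outside cannot be told apart there. Dilution by other cells is excluded by the log2 ratio of the CD8 share among T cell-like cells, -1.414 (-1.977 to -0.85), only while the mixed T cell cluster is kept apart; with it counted as CD8 the value was -0.715 (-1.04 to -0.391), an interval that holds the bound of -0.5 and leaves dilution open as a part of the difference. No biological explanation was tested.

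The larger fibroblast-like share was set against naming and sampling. Clusters named differently are excluded as the whole cause by a log2 ratio of 2.204 (2.18 to 2.229) for the CPM of fibroblast markers over all kept cells. This is below the 4.40 of the share, but the gap need not come from naming. CT26 tumour cell-like cells held 11293 of the 16162 mock and 7836 of the 82650 PTIR1 fibroblast marker UMIs, which draws the marker ratio down. The share was 1.83 with each library clustered on its own, so naming stays open as a part of the size. A larger piece of tissue holding fibroblasts and vessels alike, and more fibroblasts in the tumour, cannot be told apart: with fibroblast-like cells left out, endothelial markers had a log2 ratio of 0.309 (0.24 to 0.377), but their CPM was 40.6 in the mock library against 96.5 in NK cell-like and 113.7 in B cell-like cells, so RNA outside vessels would hide a rise. No biological explanation was tested.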

How the results depend on the processing

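No paired analysis was possible because there was 1 library per group. All values are log2 ratios, PTIR1 over mock, of shares or list medians, and the cause was not tested unless a setting names it. Of 71 values of the 5 main shares under the alternatives 46 stayed within their interval, 23 moved and 2 reversed; of 84 values of the 8 main lists 48 stayed, 36 moved and none reversed. Of the other shares 82 of 109 values stayed and 4 reversed, of the other lists 329 of 508 stayed and 15 reversed, and of the 126 ranked genes 194 of 306 values stayed and 2 reversed. The CD8 T cell-like share ran from -2.67 to -1.39.

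With at least 200 UMIs per gene macrophage-like MHC class II was -1.119. With doublets kept the macrophage-like share was -0.042, immunoproteasome -0.575, MHC class II -1.145 and interferon gamma response -0.953; dendritic cell-like MHC class II was 0.366 (reversed) and interferon gamma response -1.147. Thinned to 1000 UMIs, shares were 0.198 for NK cell-like, -0.557 for macrophage-like, 3.798 for fibroblast-like and -0.143 (reversed) for plasmacytoid dendritic cell-like cells. Macrophage-like immunoproteasome was then -0.591, MHC class II -1.009 and interferon gamma response -0.863, tumour cell-like immunoproteasome -0.114 (3 of 5 genes left) and MHC class I -0.351 (5 of 12). NK cell-like cell cycle 0.063 (11 of 18), CD4 T cell-like naive and memory 0.077 (4 of 10) and regulatory activation 0.094 (5 of 9) reversed, with fewer genes and with each cell weighing the same. With each library clustered on its own the fibroblast-like share was 1.83. By marker UMIs without clustering, shares were 0.138 for NK cell-like, 1.235 for B cell-like, -0.212 for macrophage-like, 3.45 for fibroblast-like and -0.03 (reversed) for plasmacytoid dendritic cell-like cells.

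With each cell weighing the same, macrophage-like MHC class II was -0.94, tumour cell-like immunoproteasome -0.146, MHC class I -0.243 and interferon gamma response -0.747, and neutrophil-like interferon gamma response -1.219. NK cell-like cytotoxic (-0.051) and cell cycle (0.014) genes, Ctsk in NK cell-like (0.463) and C1qa in neutrophil-like cells (-0.285) reversed. With up to 20% mitochondrial UMIs the macrophage-like share was 0.035 (reversed), immunoproteasome -0.506, MHC class II -1.041 and interferon gamma response -0.897, tumour cell-like interferon gamma response -0.941 and that of dendritic cell-like cells -1.082; dendritic cell-like MHC class II (0.476) and NK cell-like cytotoxic genes (-0.007) reversed. With up to 5% the shares were 0.706 for NK cell-like, 1.296 for B cell-like, 2.824 for fibroblast-like and -0.048 (reversed) for plasmacytoid dendritic cell-like cells. Centred on all genes, macrophage-like immunoproteasome was -0.608, MHC class II -1.037, interferon gamma response -0.975 and tumour cell-like MHC class I -0.355. The B cell-like share was 1.194 at resolution 0.5 and the macrophage-like share -0.557 at 2.0. As shares of lymphoid cells NK cell-like cells were -0.044 (reversed) and B cell-like cells 0.428. With at least 500 genes per cell the NK cell-like share was 0.329 and the macrophage-like share -0.491.

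The following settings were chosen after seeing the data. With at least 500 genes per cell macrophage-like MHC class II was -0.914 and neutrophil-like interferon gamma response -1.236. With cell cycle genes kept the macrophage-like share was -0.099. As shares of named cells NK cell-like cells were 0.236, B cell-like 0.708 and macrophage-like -0.58. With mixed clusters counted in their lymphoid class the CD8 T cell-like share was -1.394 and the NK cell-like 0.893. With the highest doublet scores removed in both libraries, the plasmacytoid dendritic cell-like share was -0.375 (reversed), macrophage-like MHC class II -0.893, tumour cell-like interferon gamma response -1.388, neutrophil-like -1.197 and dendritic cell-like -0.584, and dendritic cell-like MHC class II 0.001 (reversed). With each macrophage-like cluster weighing the same, immunoproteasome was -0.477, MHC class II -0.87, interferon gamma response -0.767 and inflammatory genes -0.079 (reversed). Within cells of like immediate early RNA they were -0.546, -0.799, -0.947 and -0.137 (reversed), and cell cycle (0.054), constitutive proteasome (0.011), lipid (0.072) and oxidative phosphorylation (0.053) genes reversed.

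Clustering each library on its own gave no CD8 T, CD4 T, tumour or migratory dendritic cell-like share, resolution 0.5 no conventional dendritic cell-like share, and thinned cells no tumour cell-like share. The CD8 T cell-like class rests on 24 PTIR1 cells.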

Other observations

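Some values belong to no comparison above. A small cluster led by Gzmg, Gzmf, Gzmd and Gzme held 4 mock and 17 PTIR1 cells and was given no class. Plasma cell-like cells numbered 2 in the mock and 47 in the PTIR1 library (0.0234% and 0.628%), gamma delta T cell-like cells 15 and 23, and migratory dendritic cell-like cells 44 and 57 (0.515% and 0.762%). The largest cluster without a class held 28.6% of mock and 8.38% of PTIR1 cells, at a median of 760 UMIs. Mast cell marker CPM were lower in the PTIR1 library in NK cell-like (ratio 0.181), B cell-like (0.262) and neutrophil-like cells (0.240), classes that do not express them.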
